A study of Homo sapiens with 15 samples.

How the data were processed

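Total RNA of IMR32 cells carrying an inducible hairpin against CDK2 was measured on 15 Affymetrix U133 Plus 2.0 arrays, 3 at each of 5 times after doxycycline (0, 8, 24, 48 and 72). The labels give the times without a unit, and hours were taken from knowledge of the study. Per the labels, cells grew in 10% fetal calf serum, 4 µg of RNA was labelled by the one-cycle protocol, and values came from MAS5 and GCOS, with no versions stated. The deposited table holds a linear signal intensity for each of 54675 probe sets. The trimmed mean (2% at each end) was 100.01 in all 15 arrays, so the values were used as deposited. The number of arrays limits the precision.

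Of the probe sets, 62 were controls, 41091 named 1 gene, 1801 named several and 11721 named none. Values were taken as log2(value + 16). A probe set entered if its mean log2 value over all arrays was at or above the median of the probe sets that are not controls (a signal of about 16.6), which 27307 passed. Of the probe sets naming exactly 1 gene, the one with the highest mean stood for the gene, leaving 11774 genes.

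The 5 times were fitted together with limma (3.58.1, lmFit and eBayes with trend=TRUE) in R 4.3.3, with 3 arrays per group. Comparisons were each later time against 0 h, each time against the one before, and a moderated F test over the 4 differences from 0 h. P-values were adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05. The rule for naming genes and the lists were fixed before the data were examined. Of each comparison with 0 h, the named genes are the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 arrays do not overlap those at 0 h (10% of genes with no change have such a separation in 3 against 3). Added to these are up to 4 members past the threshold of each list, those with the greatest change, and 22 sentinel genes at all times. HS6ST2, ATR, PMAIP1, TP53I11, TUBB3, RBL1, CDK6, BID, PGK1, COL1A1, PECAM1 and KRT8, and ATM, BIRC2, DBH, E2F5, RBL2 and YWHAZ at some times, fall outside this rule and were named after their values were seen. Of the sentinel genes 18 were measured. BBC3 lay only on a probe set naming several genes, and MYC lay below the filter. The remaining sentinel genes are not reported here.

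The 18 gene lists were p53 targets, G1/S and DNA replication genes, G2/M and mitosis genes, cyclins with CDKs, CDK inhibitors and pocket proteins, apoptosis regulators, MYC/MYCN-activated ribosome biogenesis and growth genes, noradrenergic neuronal genes, mesenchymal neuroblastoma and Schwann cell genes, fibroblast, immune, endothelial and epithelial markers, interferon response, ATF4 and endoplasmic reticulum stress, hypoxia and glycolysis, cholesterol synthesis, immediate early genes, DNA repair and checkpoint genes, ribosomal proteins, oxidative phosphorylation, and reference genes. In all 11 genes stand in more than 1 list. Each list was tested at each time against 0 h with limma's camera at a preset correlation of 0.01, with adjustment over the 72 tests, and with an estimated correlation and with fry beside it. Fry tests whether the genes of a list move, on balance, 1 way, and does not compare them with other genes. Calls were also counted with adjustment over each list alone. Overlaps were set against n1 x n2 / N and against 20 simulations of unchanged groups sharing the 0 h arrays.

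Nothing in the labels says that equal replicate numbers pair the arrays. Residuals of arrays with the same number correlated at -0.08 to 0.35 (median 0.12) over 30 pairs and those with different numbers at -0.28 to 0.17 (median -0.08) over 60 pairs, and for 10 of 15 arrays the best partner carried its own number. All 3 pairs exceeded 0.1 for 48 h with 0 h (0.12 to 0.21) and for 72 h with 48 h (0.12 to 0.35). Adding the replicate number as a block gave 5580 genes for the former and 1732 for the latter comparison, against 5175 and 1258 without it.

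Alternatives changed the pseudocount (1 or 64), the scaling between arrays (quantile normalisation, or centring each array on its median), the filter (none, or the brightest 25% of probe sets), the probe sets per gene (their mean, or all probe sets tested singly), the variance prior, array weights, the arrays in the fit, a replicate block, and a stricter threshold (an absolute log2 change of 1 in addition). Each array was also left out in turn. Fits without any replicate 3 array, or without those of 8 h and 72 h alone, were added after the data were seen. The test was also run on simulated data with 50 changed genes at each size. For 8 h against 0 h it recovered 4, 30, 49 and 50 of them at log2 changes of 0.25, 0.5, 1 and 2. In 1 simulated data set with nothing changed, 0 lists were called. Its genes varied independently of each other, so it cannot show how the list test behaves when genes of a list are correlated. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures. Transcript sequences were not searched here.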

Results

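The series followed IMR32, an established human neuroblastoma cell line with amplified MYCN, after induction of a short hairpin RNA against CDK2, the cyclin-dependent kinase that acts with cyclins E and A at the entry into and passage through S phase. The hairpin targets nucleotides 546 to 566 of the CDK2 mRNA and is under a tetracycline repressor, so that doxycycline (100 ng/ml) switches it on. RNA was taken at 5 times, 0, 8, 24, 48 and 72, with 3 arrays each, 15 Affymetrix U133 Plus 2.0 arrays in all. The labels give these times without a unit, and they are read here as hours from knowledge of the study. The design asks which transcripts change as CDK2 is depleted. It holds no arm without doxycycline or with another hairpin at the later times, so time in culture, doxycycline and the knockdown cannot be told apart in any comparison with 0 h. Nothing in the labels says whether the 3 arrays of a time come from separate cultures, so the p-values measure only the spread between these arrays.

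Median signal rose on average with time, while the control ratios and the 18S ribosomal RNA control went up and down. The ratio of the 3′ to the 5′ GAPDH control probe set lay between 0.974 and 1.07, and that of ACTB between 1.10 and 1.35. The ACTB ratio was 1.14 ± 0.046 at 0 h, 1.21 ± 0.097 at 8 h, 1.22 ± 0.021 at 24 h, 1.19 ± 0.046 at 48 h and 1.26 ± 0.077 at 72 h (SD, n = 3). Median signal was 16.3 ± 0.666, 16.7 ± 1.65, 17.6 ± 0.404, 18.5 ± 0.862 and 18.9 ± 1.60 intensity units at 0, 8, 24, 48 and 72 h (SD, n = 3), and ranged from 15.1 to 20.5 over the arrays. The 18S ribosomal RNA control read 148.0 ± 15.7 at 0 h, 150.9 ± 46.9 at 8 h, 179.5 ± 91.4 at 24 h, 138.7 ± 62.3 at 48 h and 250.1 ± 116.2 at 72 h. In limma's array weights the lowest were 0.356 for 72 h replicate 3 and 0.405 for 8 h replicate 3. Log2 values correlated at 0.982 to 0.989 across probe sets between arrays of the same time and at 0.955 to 0.989 between arrays of different times. The 8 h replicate 3 array read 947.9 at a spiked control transcript (DapX), where the other arrays read 321.8 to 576.8. Its mean correlation with its own group was 0.983, as was that of 72 h replicate 3, and the others had 0.985 or more. On the first principal component of the tested genes, 65.9% of the variance, the groups lay in order of time without overlap. On the second, 8.94%, replicate 3 had the highest score at each time. The number of arrays per time limits the precision of all values given here.

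CDK2 fell at all 4 times after induction. Its brightest probe set, which stands for the gene in the tests, read 231.7 ± 16.3 (SD, n = 3) at 0 h, 94.5 ± 5.56 at 8 h, 80.4 ± 7.72 at 24 h, 48.6 ± 7.36 at 48 h and 30.1 ± 9.90 at 72 h (n = 3 each). On the log2 scale the changes against 0 h were -1.16, -1.36, -1.94 and -2.45, each with a standard error of 0.14, and the 3 arrays of each time lay below the 3 arrays at 0 h. The adjusted p-values from limma were 4.6e-04, 3.7e-06, 8.3e-09 and 1.2e-10. The step from 8 h to 24 h was -0.20 ± 0.14 (SE, adjusted p = 0.47), that from 24 h to 48 h -0.58 (adjusted p = 0.0062) and that from 48 h to 72 h -0.50 (adjusted p = 0.030). A dimmer CDK2 probe set went from 107.3 ± 15.2 at 0 h to 41.2 ± 23.2 at 8 h and 14.4 ± 3.45 at 72 h (SD, n = 3), and its 8 h change of -1.19 missed the threshold when all probe sets were tested together (adjusted p = 0.053). The remaining CDK2 probe set lay near background throughout, with means of 1.93 to 5.37. The genomic position of the target site was not analysed here.

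**Figure D1:**
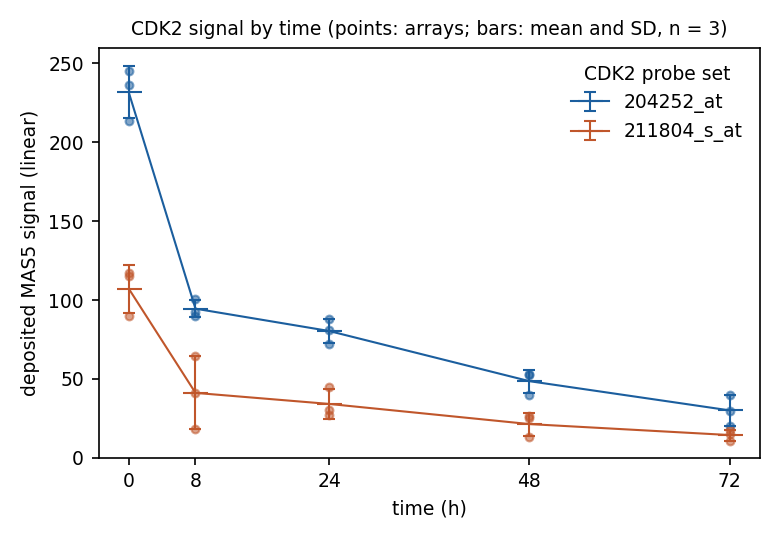
Deposited signal of CDK2 (y axis, linear intensity) by time in hours (x axis) for the probe sets of the gene that passed the filter; points are single arrays, and lines join the means with bars of 1 SD (n = 3). The brightest goes from a mean of 231.7 at 0 h to 30.1 at 72 h.

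Of the 11774 genes tested, 6713 changed over the time course by the moderated F test. The number called against 0 h was 53 at 8 h, 1584 at 24 h, 5175 at 48 h and 6531 at 72 h. Most changes were small: 2 genes at 8 h (both lower), 70 at 24 h (23 higher, 47 lower), 575 at 48 h (279 and 296) and 1212 at 72 h (629 and 583) also passed an absolute log2 change of 1. The median change of all tested genes was 0.02, 0.05, 0.08 and 0.10 at these times. Centring each array on its median moves the 72 h median from 0.10 to -0.003, a shift of over 0.1 against which the small changes below have to be read. Values are those of 1 probe set per gene. Of the named genes called, 11 of 20 at 8 h, 33 of 66 at 24 h, 53 of 94 at 48 h and 52 of 95 at 72 h had other probe sets past the filter, and for 8, 10, 7 and 4 of these no other probe set was called in the same direction. Here and below, other probe sets were called from a fit of all probe sets past the filter, adjusted over those. That is not the adjustment over 11774 genes, so a probe set may change as much and not be called. CDK2 at 8 h is among the 8, with -1.19 on its other probe set and -1.16 on the one used.

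**Figure D2:**
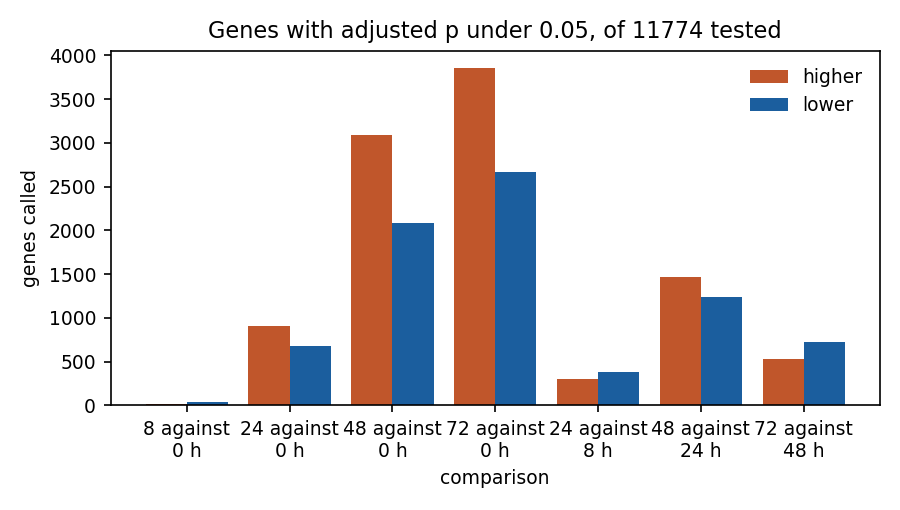
Number of genes called higher (orange) and lower (blue) at an adjusted p under 0.05 (y axis) in each comparison of times (x axis). Against 0 h the calls go from 11 higher and 42 lower at 8 h to 3861 higher and 2670 lower at 72 h.

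At 8 h, 42 genes fell and 11 rose. After CDK2 the falls with the greatest size were those of RAB7A, a small GTPase of late endosomes (-1.05 ± 0.11, SE), LIPA, the lysosomal acid lipase (-0.99 ± 0.10), PSMD10, a proteasome assembly factor (-0.97 ± 0.13), PIP4P2 (-0.96 ± 0.17) and CFAP70 (-0.88 ± 0.18). LIN7C, DCPH1, IDH3A, a subunit of the mitochondrial isocitrate dehydrogenase, and PM20D2 fell by 0.81, 0.80, 0.76 and 0.76. The other PSMD10 probe set was called lower too (-1.24), as was 1 of 4 others of RAB7A (-1.06 to -0.14) and 1 of 2 others of LIN7C (-0.81 and -0.41). The largest rises were smaller: TRIM46 (0.60 ± 0.12), GOLGA8A, SGSM2, INPP5E and PCED1A (0.58 each), NPIPA1 (0.56), DENND4B (0.54), R3HDM2 (0.50), FAM193B (0.45) and RAB24 (0.42), with adjusted p-values from 0.0095 to 0.039. Other probe sets were not called for TRIM46 (-0.19), GOLGA8A (0.14), PCED1A (0.19), FAM193B (0.07) and SGSM2 (0.16 and 0.43), nor for the falls IDH3A (-0.53) and PM20D2 (-0.70). No sentinel gene other than CDK2 passed the test. CDKN1A, the CDK inhibitor p21, was at 0.31 ± 0.10 (adjusted p = 0.24), CDKN1B at 0.34 ± 0.12 (0.33), MDM2 at 0.18 ± 0.11 (0.67) and CCNA2 at 0.13 ± 0.13 (0.81). The 53 calls (11 higher, 42 lower) became 25 (2 higher, 23 lower) without 0 h replicate 1, 20 (2 and 18) without 0 h replicate 2, 32 (1 and 31) without 0 h replicate 3, 30 (5 and 25) without 8 h replicate 1 and 24, all of them lower, without 8 h replicate 2. They became 102 (37 and 65) with array weights and 88 (25 and 63) with replicates 1 and 2 alone, a setting chosen after the data were seen.

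The genes that fell at 8 h were also lower later. All 42 were called lower at 24 h, 39 at 48 h and 37 at 72 h. Independent lists of these sizes would share 2.40, 7.43 and 9.52 genes. In 20 simulations of unchanged groups sharing the 0 h arrays the overlap was 0, but unchanged groups give almost no calls at the adjusted threshold. At an unadjusted p under 0.05 it was 61.8 genes on average for 8 h and 24 h, against 221 observed, from lists of unlike size. The simulations therefore do not measure what the shared 0 h arrays add, and part of the excess may come from those arrays. Leaving CDK2 aside, the median change of the other 41 genes was -0.64 at 8 h, -1.04 at 24 h, -0.97 at 48 h and -1.02 at 72 h. HS6ST2, named after its values were seen, was called higher at 72 h, by 0.27, after falls of 0.73 at 8 h and 0.63 at 24 h.

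**Figure D3:**
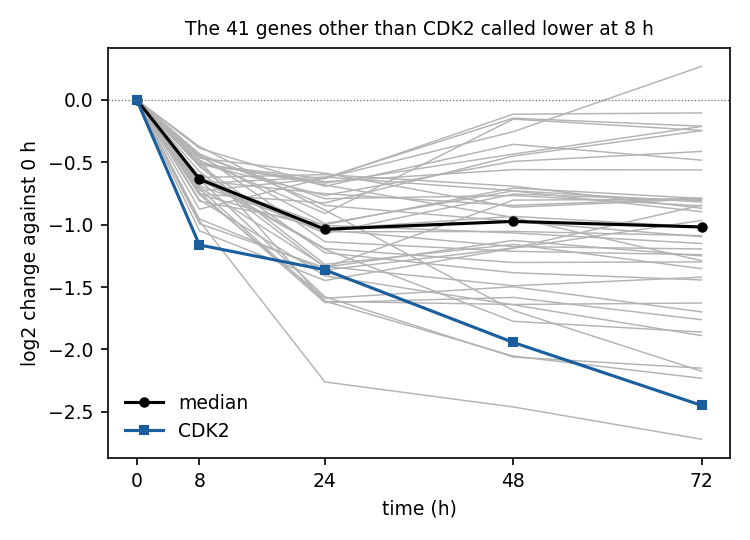
Log2 change against 0 h (y axis) by time in hours (x axis) of the 41 genes other than CDK2 called lower at 8 h (grey lines, 1 per gene), their median (black) and CDK2 (blue). The median goes from -0.64 at 8 h to -1.02 at 72 h. The genes were drawn because they fell at 8 h.

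At 24 h, 911 genes rose and 673 fell. Genes induced by p53 rose together: 20 of the 32 measured members of that list rose, all 32 had positive changes, and the median change was 0.50. SESN1 and SESN2, which encode sestrins, rose by 1.41 ± 0.12 and 1.19 ± 0.15 (SE), CDKN1A by 1.27 ± 0.10, RRM2B, a ribonucleotide reductase subunit, by 0.86 ± 0.10, and MDM2, which encodes the ubiquitin ligase of p53, by 0.47 ± 0.11. The greatest rises of all were TMT1A (2.25), DDIT4, an inhibitor of mTORC1 signalling (1.53), SESN1, PLXNB1 (1.32), MUC19 (1.32), CELF3 (1.27), CDKN1A, MAMDC4 (1.27), TXNIP (1.24) and TAFA2 (1.20). The greatest falls were PSMD10 (-2.26), TOMM20, a receptor of mitochondrial protein import (-1.63), ARF4, a GTPase of the Golgi (-1.62), SPIN4 (-1.61), IDH3A (-1.59), KIFBP (-1.58), TCEAL9 (-1.48), RAB7A (-1.45), DCPH1 (-1.41) and DBI (-1.40). Other probe sets gave 0.19 to 0.99 for TMT1A (1 of 3 called), 0.81 for CELF3 (not called) and -1.53 to 0.10 for RAB7A (2 of 4 called). Those of TXNIP, PSMD10, TOMM20, ARF4, IDH3A and DBI were called in the same direction. Of the G1/S and DNA replication genes 10 of 38 fell, led by GINS3 (-1.31), MCM10 (-0.77) and SLBP (-0.71), and of the G2/M and mitosis genes 3 of 36 (KIF14, -0.60; PRC1, -0.57; ANLN, -0.41). The other probe sets of KIF14 (-0.23) and ANLN (-0.29) were not called.

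Adjusted over the list alone, 26 p53 targets rose at 24 h, 12 G1/S genes fell and 3 G2/M genes fell. Limma's camera test, which compares a list with all other genes at a preset correlation of 0.01, gave adjusted p = 5.2e-17 for the p53 targets and 5.6e-08 for the G1/S genes (median -0.18) at 24 h. With an estimated correlation these were adjusted p = 0.072 and 0.45. For the G2/M genes it gave 0.20 (median -0.01, or 0.02 with quantile normalisation). The 1584 calls became 1006, 1039 and 1014 without 0 h replicates 1, 2 and 3, and 1025 and 1019 without 24 h replicates 1 and 3. With each array centred on its median the split of 911 higher to 673 lower became 539 to 938.

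At 48 h, 3093 genes rose and 2082 fell. All 38 measured G1/S and DNA replication genes and all 36 G2/M and mitosis genes fell, with medians of -1.42 and -1.29. MCM10, which acts in the start of replication, fell by 2.45 ± 0.11 (SE), CDC25A, a phosphatase that activates CDK2, by 2.22 ± 0.15, and CDC6, a licensing factor of replication origins, by 2.08 ± 0.08. In the mitotic list HMMR fell by 2.48 ± 0.22, and the kinesins KIF11 and KIF14 were called lower, at -1.98 ± 0.15 and -1.97 ± 0.13. Of the DNA repair and checkpoint genes 20 of 22 fell, led by BRCA1 (-1.82) and EXO1 (-1.79), while ATM (0.56) and ATR (0.30) rose. Of the p53 targets 30 of 32 rose (median 0.83; SESN1 1.92, RRM2B 1.88, CDKN1A 1.61, CYFIP2 1.54), and PMAIP1 and TP53I11 fell (-0.34 and -0.79). The greatest rises were TMT1A (3.76), the histone genes H2AC25 (3.36) and H2AC6 (3.16), MUC19 (2.64), MYCT1 (2.49), PURPL (2.46), HDAC9 (2.45), SLC44A5 (2.35), DDIT4 (2.35) and LUM (2.31). Falls outside the cell-cycle lists included IGFBP5 (-2.64), PSMD10 (-2.46), DBI (-2.30) and UNKL (-2.21).

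At 72 h, 3861 genes rose and 2670 fell. All measured members of the G1/S list (median -2.11) and of the G2/M list (median -2.66) were again called lower. HMMR fell by 4.46 ± 0.22 (SE), PBK by 3.63 ± 0.16, PRC1 by 3.36 ± 0.14 and MCM10 by 3.33 ± 0.11. CDK1, the mitotic kinase, fell by 3.19 ± 0.22, SHCBP1 fell by 3.15 ± 0.15 and ANLN fell by 3.06 ± 0.12. Among the sentinels other than CDK2 and CDK1, the falls were BIRC5 (-3.01), CCNE2 (-2.43), CCNA2 (-2.40), MKI67 (-2.28), E2F1 (-1.64), PCNA (-1.47) and CCNE1 (-0.90). CDK4 was at -0.07 ± 0.07 (adjusted p = 0.40), CDKN1B at -0.01 ± 0.12 (0.96) and CCND1 at -0.19 ± 0.08 (0.060), while the other CCND1 probe set was called lower, at -0.65. With the arrays centred on their medians CDK4 and CCND1 passed the test as falls, at -0.18 and -0.29. Of the p53 targets 30 rose and 2 fell (median 0.97), with RRM2B at 2.37, SESN1 at 2.11, CYFIP2 and PLK2 at 1.99, CDKN1A at 1.88, TP53INP1 at 1.65, MDM2 at 1.11 and BAX at 0.67. TMT1A (4.58, 23.9-fold), H2AC25 (4.21, 18.5-fold), H2AC6 (3.99, 15.9-fold), MUC19 (3.85), RET, a receptor tyrosine kinase of neural crest derivatives (3.63, 12.4-fold), LUM (3.61), HDAC9 (3.58), MYCT1 (3.57), SLC44A5 (3.33) and H2BC5 (3.28) rose most. Other probe sets gave smaller changes for TMT1A (0.31 to 3.28, 2 of 3 called), RET (1.73 and 1.97), MYCT1 (1.67), SLC44A5 (1.59 to 2.52) and H2BC5 (2.43). The folds given include the pseudocount of 16, which compresses those of genes dim at 0 h. H2AC6 read 16.9 at 0 h and 509.8 at 72 h, and LUM read 13.7 and 346.3.

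The camera test called the G1/S, G2/M and DNA repair lists and the p53 targets at both late times. For the G1/S genes the adjusted p was 2.7e-34 at 48 h and 1.2e-32 at 72 h (adjusted p = 0.11 at both times with an estimated correlation). For the G2/M genes it was 1.6e-26 and 1.2e-32 (0.22 and 0.15 with an estimated correlation, as adjusted p). For the DNA repair genes it was 4.6e-14 and 1.8e-14, and these calls held with an estimated correlation (adjusted p = 0.034 at both times). For the p53 targets it was 5.0e-12 and 3.8e-11 (adjusted p = 0.11 and 0.12 with an estimated correlation). Adjusted over each list alone the calls at 48 h and 72 h were the same in number: 38 lower for G1/S, 36 lower for G2/M, 20 lower and 2 higher for DNA repair, and 30 higher and 2 lower for the p53 targets. At 8 h the G2/M list was called in the other direction (median 0.14, adjusted p = 5.6e-04), with 33 of 36 members above their 0 h value, although no member passed limma's test (6 higher and 0 lower at an unadjusted p under 0.05). That call was lost with an estimated correlation (adjusted p = 0.77), with fry (0.46), and without 8 h replicate 1. With each array centred on its median the split of 3093 higher to 2082 lower at 48 h became 2257 to 2673, and that of 3861 to 2670 at 72 h became 2922 to 3316.

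**Figure D4:**
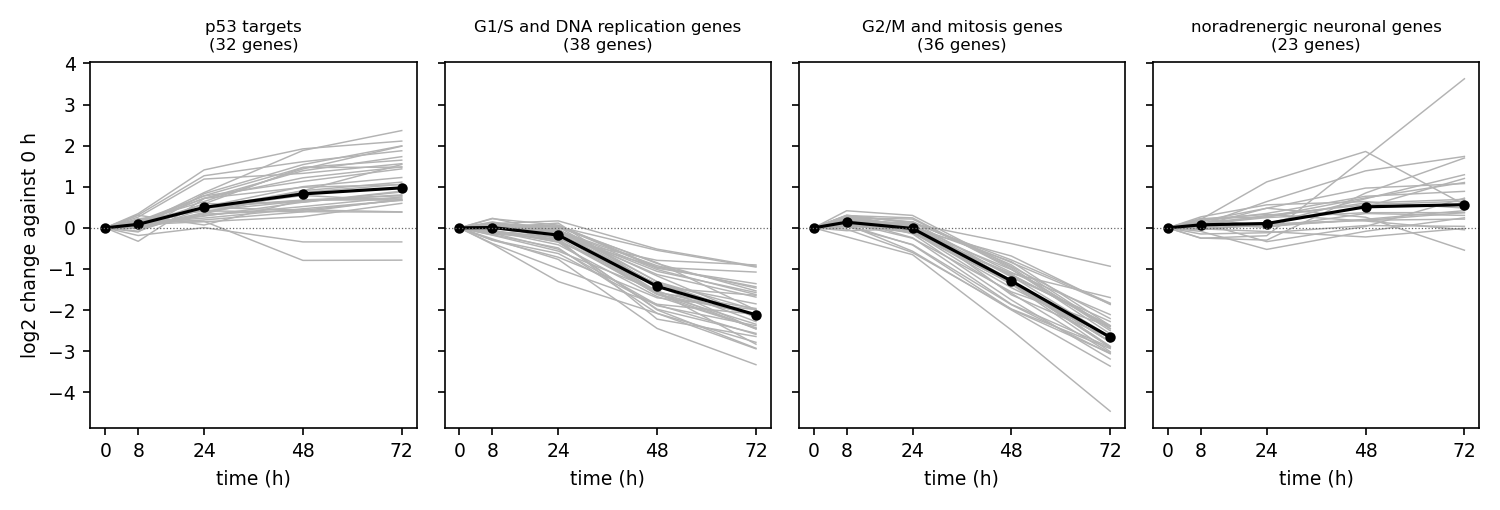
Log2 change against 0 h (y axis) by time in hours (x axis) of each measured member (grey lines) of 4 gene lists fixed before the data were examined, with the list's median in black. The median of the p53 targets is at 0.50 at 24 h and 0.97 at 72 h, that of the G1/S genes at -0.18 and -2.11, that of the G2/M genes at -0.01 and -2.66 and that of the noradrenergic genes at 0.11 and 0.56.

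More noradrenergic neuronal genes were called higher at 48 h and 72 h than at 24 h, as was so for all 11774 genes (911, 3093 and 3861 at 24, 48 and 72 h). Of 23 measured, 5 rose and 1 fell at 24 h, 14 rose and 1 (TUBB3, -0.22) fell at 48 h, and 18 rose at 72 h, where the median was 0.56. DBH, the enzyme that makes noradrenaline, rose by 1.12 ± 0.20 (SE) at 24 h and 1.86 ± 0.20 at 48 h, and was at 0.56 at 72 h (adjusted p = 0.024). ISL1, a homeobox transcription factor, rose by 0.64, 1.39 and 1.74 at 24, 48 and 72 h, and HAND2 by 0.97 at 48 h. SCG2, a granule protein, and NEFL, a neurofilament subunit, rose by 1.70 and 1.29 at 72 h. CHGA fell by 0.52 at 24 h. Adjusted over the list alone, 6 rose and 1 fell at 24 h, 14 rose and 1 fell at 48 h, and 18 rose and 1 fell at 72 h. Camera gave adjusted p = 0.11 at 24 h, 6.7e-04 at 48 h and 5.0e-04 at 72 h, and with an estimated correlation the late calls were lost (adjusted p = 0.22 at both times). MYCN was at 0.23 ± 0.08 at 48 h (adjusted p = 0.027) and 0.21 ± 0.08 at 72 h (0.035). Both calls were lost with the arrays centred on their medians (0.14 and 0.11), as were those of ALK (0.35 and 0.30, then 0.26 and 0.20). The 3 other MYCN probe sets were at 0.18 to 0.39 at 48 h (0 called) and at -0.02 to 0.60 at 72 h (1 called).

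Genes of ribosome biogenesis and growth that MYC proteins activate were called lower more often than higher, mostly with small changes. Of 25 measured, 4 fell at 24 h, 8 fell and 3 rose at 48 h, and 13 fell and 1 rose at 72 h (median -0.18), led by CDCA7 (-1.34), TERT (-0.68), RRS1 (-0.56) and ODC1 (-0.50). Of all 11774 genes 673, 2082 and 2670 fell and 911, 3093 and 3861 rose at these times. Camera called the list at 24, 48 and 72 h (adjusted p = 0.021, 0.020 and 0.016), and none of these calls held with an estimated correlation (adjusted p = 0.45 at each time). At 24 h and 48 h the call was also lost with quantile normalisation. Adjusted over the list alone, 13 fell and 2 rose at 72 h. Ribosomal protein genes showed 8 rises of 18 at 72 h (RPL19 0.45, RPL3 0.36; 6 adjusted over the list alone; camera adjusted p = 0.16), and the call of RPL3 was lost with the arrays centred on their medians (0.26). Of 26 oxidative phosphorylation genes 5 rose and 6 fell at 72 h (NDUFA10 0.61, NDUFS1 -0.46; the same numbers adjusted over the list alone; median 0.03, or -0.08 with centred arrays, camera direction lower, adjusted p = 0.67). Among them, ATP5F1C had probe sets called in opposite directions (-0.53 and 0.58), and the other NDUFA10 probe set was at 0.10 and was not called.

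The remaining regulators of the cycle changed in both directions. Among 28 cyclins, CDKs, inhibitors and pocket proteins, 5 rose and 11 fell at 72 h. Besides CDK2 and CDKN1A, WEE1, which restrains CDK1, fell by 1.74, CKS1B by 1.70, PKMYT1 fell by 1.64 and RBL1 by 1.14, while E2F5 rose by 0.96, CDK6 by 0.64 and RBL2 by 0.50. The 28 include CDK2, the target of the hairpin, so part of the downward shift of the list was set by the design. Camera gave adjusted p = 0.046 at 48 h and at 72 h, and with an estimated correlation adjusted p = 0.22 at both times. Both calls were also lost with quantile normalisation. Of 22 apoptosis regulators 6 rose and 5 fell at 72 h, when 3861 and 2670 of all 11774 genes did. The death receptors TNFRSF10B and FAS rose by 1.48 and 1.44, and BCL2, which restrains apoptosis, by 1.68, although the other BCL2 probe set was at 0.07 and was not called. The 2 other TNFRSF10B probe sets were at 0.48 and 0.78 (1 called), and the 3 others of FAS at 1.11 to 1.18 (all called). BIRC2 and BID fell by 0.36 and 0.37 (camera adjusted p = 0.69). Adjusted over the list alone, 5 rose and 13 fell in the former list and 6 rose and 5 fell in the latter.

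Stress and metabolic lists were mixed. Of 29 ATF4 and endoplasmic reticulum stress genes 4 rose and 16 fell at 48 h. SLC7A5, an amino acid transporter subunit, fell by 1.32 and CEBPB by 1.14, whereas DDIT4 rose by 2.35 and SESN2 by 1.33. Camera gave adjusted p = 0.0055 at 48 h (adjusted p = 0.33 with an estimated correlation) and 0.10 at 72 h, where 7 rose and 16 fell. Of 26 hypoxia and glycolysis genes 8 rose and 11 fell at 72 h (VEGFA 1.12, PDK1 0.96, PKM -0.83, with its other probe set not called at -0.29; camera adjusted p = 0.37). Of 17 cholesterol synthesis genes 3 rose and 6 fell at 72 h (STARD4 1.57, ACAT2 -1.83, FDPS -1.07; camera adjusted p = 0.20). Of 15 immediate early genes 6 rose and 3 fell at 72 h (ARC 2.43, DUSP6 2.29, NR4A2 -1.35; camera adjusted p = 0.52). Of 11 interferon response genes 3 rose and 3 fell at 72 h (ISG15 1.04, IFI44 -2.26; median 0.06, or -0.04 with centred arrays, camera direction lower, adjusted p = 0.90). Adjusted over the list alone the calls were 4 higher and 17 lower for ATF4 at 48 h, 8 and 12 for hypoxia, 3 and 6 for cholesterol, 6 and 3 for the immediate early and 3 and 3 for the interferon genes.

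Genes often used as references were not level. Of 10 measured, B2M, the light chain of MHC class I, fell by 1.25 at 24 h, 1.53 at 48 h and 1.74 ± 0.08 (SE) at 72 h. HPRT1 fell by 1.12 and GUSB by 1.01 at 72 h, and TBP, YWHAZ and PGK1 by 0.29, 0.20 and 0.17. Camera called the list at 24, 48 and 72 h (adjusted p = 0.048, 0.0069 and 0.0072), with adjusted p = 0.45, 0.27 and 0.27 with an estimated correlation, and the 24 h call was lost under 17 of 32 other settings. Markers of other cell types were mostly dim. Of 20 fibroblast, immune, endothelial and epithelial markers 5 passed the filter, of which LUM, an extracellular matrix proteoglycan, rose by 3.61 and THY1 by 0.61 at 72 h, while COL1A1 was at 0.04, PECAM1 at 0.02 and KRT8 at -0.01 (median 0.04, or -0.06 with centred arrays; camera adjusted p = 0.38). Of 12 mesenchymal neuroblastoma and Schwann cell genes 2 rose and 5 fell at 72 h (SNAI2 -1.30, ANXA2 -0.92, FN1 0.82; camera adjusted p = 0.16). Adjusted over the list alone, 6 reference genes fell, 2 of the other cell type markers rose, and 2 mesenchymal genes rose and 5 fell, at 72 h.

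Direct tests between consecutive times called 681 genes from 8 h to 24 h (299 higher, 382 lower), 2702 from 24 h to 48 h (1462 higher, 1240 lower) and 1258 from 48 h to 72 h (535 higher, 723 lower). The count from 8 h to 24 h was 431 without 24 h replicate 1, 390 without 8 h replicate 3, 370 without 24 h replicate 3, and 340 when only these arrays were fitted. That from 48 h to 72 h was 746 without 48 h replicate 1, 656 without 48 h replicate 2 and 767 without 72 h replicate 3. With the arrays centred on their medians the split from 8 h to 24 h became 207 higher to 466 lower, and that from 24 h to 48 h turned to 1205 higher and 1369 lower. Without centring, the genes from 24 h to 48 h that also passed an absolute log2 change of 1 were 62 higher and 171 lower.

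The calls at 48 h and 72 h shared 2714 rises and 1854 falls. Independent lists of these sizes would share 1014 and 472.1. With the arrays centred on their medians the calls shared 1953 rises and 2416 falls. In 20 simulations of unchanged groups sharing the 0 h arrays no overlap arose at the adjusted threshold, where unchanged groups give almost no calls. At an unadjusted p under 0.05 the mean overlap was 61.8 rises and 61.7 falls, against 3133 and 2098 observed, from lists of unlike size. The simulations therefore do not measure what the shared 0 h arrays add. The 0 h arrays were not divided between the comparisons, and part of the excess may come from them.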

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

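The tests of the 8 h falls, of the histone genes and of LUM below were chosen after these results were seen, while the splits of the arrays were planned.

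The change from 0 h differed between consecutive times for 681 genes (24 h against 8 h), 2702 genes (48 h against 24 h) and 1258 genes (72 h against 48 h), each by a direct limma test. CDK2 differed in the same way, with -0.58 from 24 h to 48 h and -0.50 from 48 h to 72 h. Outside the gene test, 1728 of 4484 probe sets that name no gene or several passed the threshold at 72 h (1213 higher, 515 lower). Below the filter on dim signal, 1288 of 27306 probe sets passed it (1004 higher, 284 lower). Groups of 3 arrays were not tested for single arrays that stand apart.

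For the count of 6713 genes changed over time, 1 of 100 splits of the 15 arrays, the real one, gave as many, and the highest of the others gave 2040. This bears on the count and not on each gene. The splits also take the arrays as independent, which the labels do not state. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 53 and 1 (8 h), 1584 and 0 (24 h), 5175 and 0 (48 h), 6531 and 0 (72 h), 681 and 0 (24 h against 8 h), 2702 and 1 (48 h against 24 h) and 1258 and 0 (72 h against 48 h). Both kinds of split put arrays of different times into 1 group, where any real difference between times widens the spread. The lower counts of the other splits therefore do not show what unchanged arrays would give.

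Most genes called at 8 h fell, 42 of 53. Scaling between arrays did not account for it: under quantile normalisation and median centring at least 85.7% of the calls were falls. The 8 h replicate 3 array did not carry them, since 40 falls were called without it, but the number does rest on others: it was 23, 18 and 31 without 0 h replicates 1, 2 and 3, and 25 and 24 without 8 h replicates 1 and 2. Of the 41 genes other than CDK2, 87.8% were called lower at 72 h too, which silencing of other transcripts by the hairpin would give, but lasting effects of lower CDK2, of doxycycline or of time in culture would give it as well, and these cannot be told apart without a second hairpin or a search of the transcript sequences.

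Of 22 replication-dependent histone genes, gathered after some were seen among the largest rises and not tested for enrichment, 16 were called higher at 72 h and 6 were not called (3861 of all 11774 genes were called higher). The filter used the mean over all arrays, so genes dim at 0 h entered only through later signal, which may raise this share. H2AC8, for example, read 2.77 at 0 h and 92.5 at 72 h. The 15 probe sets with a plain suffix had a median change of 1.40 (11 called higher), as did the 10 whose suffix marks shared sequence (8 called higher). The suffix does not measure shared signal, and some plain probe sets were dim at 0 h. Signal shared between near-identical histone genes therefore stays open. A change in the share of histone mRNA that carries a poly(A) tail, on which the labelling relies, was not tested, and no biological explanation was tested.

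LUM, a matrix proteoglycan found in fibroblasts, went from a mean signal of 13.7 ± 3.70 at 0 h to 346.3 ± 42.7 at 72 h (SD, n = 3). Fibroblasts mixed into the cultures would bring other transcripts too, and 0 of 5 gained as much signal, but signals of different probe sets are not on 1 scale, and all but COL1A1 lay below the filter, so this cannot be told apart. COL1A1 read 289.3 and 300.9, COL1A2 13.6 and 7.40, COL3A1 4.57 and 13.7, DCN 10.7 and 14.9, and POSTN 2.73 and 2.93, at 0 h and 72 h. THY1, which fibroblasts and neurons both express, went from 97.5 to 155.6 and was called higher, and fibroblasts, time in culture and the knockdown all stay open.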

How the results depend on the processing

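Fits with replicates 1 and 2 alone and without the replicate 3 arrays at 8 h and 72 h were chosen after the data were seen, and the others before the data were examined. CDK2 kept its direction and its call at all 4 times under each alternative that gave a value (it is not among the brightest 25% of probe sets, so that filter gave none, and the robust prior was not applied to the lists). With all probe sets past the filter tested singly the counts were 12647 over time, 9460 at 48 h, 12684 at 72 h, 4063 from 24 h to 48 h and 8335 shared by 48 h and 72 h, because more features were tested. With an absolute log2 change of at least 1 they were 1247 over time, 2, 70, 575 and 1212 at 8, 24, 48 and 72 h, 17, 233 and 114 between consecutive times, and 541 shared, which follows from the added threshold. At 8 h, array weights gave 102 and replicates 1 and 2 alone 88. Only the 2 groups compared gave 340 from 8 h to 24 h, and the replicate block with quantile normalisation 1921 from 48 h to 72 h. Fry called 30 list shifts (12 higher, 18 lower) in place of 22: 2 of the 22 were lost and 10 others were added. Among those added were the noradrenergic genes at 24 h (fry adjusted p = 0.023) and the apoptosis regulators at 72 h (2.1e-06). Fry does not compare a list with other genes, so the 2 counts answer different questions. With an estimated correlation 2 list shifts were called by camera in place of 22. The estimates ran from -0.01 (apoptosis regulators) to 0.87 (ribosomal proteins), with 0.18 for the p53 targets, 0.47 for the G1/S and 0.67 for the G2/M genes. Estimates above the preset 0.01 widen the variance that camera uses, so part of the loss follows from them. Apart from the added threshold, the all-probe-set counts, the estimated correlation and the fits with fewer arrays or genes, the cause was not tested.

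Leaving out 1 array gave 20 to 70 genes at 8 h, 1006 to 1843 at 24 h, 370 to 842 from 8 h to 24 h and 656 to 1450 from 48 h to 72 h. The replicate block gave 7262 over time, 57, 1991, 5580 and 6878 against 0 h, and 958, 3188 and 1732 between consecutive times. Of the named genes called, 14 of 20 at 8 h, 27 of 66 at 24 h, 12 of 94 at 48 h and 8 of 95 at 72 h lost their call under at least 1 alternative, and no call reversed. Of the 22 list calls 15 held under each alternative except an estimated correlation, and 7 were lost under another too. Signals near the filter, about 16.6, are compressed by the pseudocount: CDK2 at 72 h was -2.95 with a pseudocount of 1 and -1.66 with 64.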

Other observations

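The genes named in this part were chosen after their values were seen, as was the test of the p53 targets below. Of 22 replication-dependent histone genes, not tested as a group, 2 were called higher at 24 h, 12 at 48 h and 16 at 72 h, when of all 11774 genes 911, 3093 and 3861 were. Their median was 1.25 at 72 h. Here too, histone genes dim at 0 h could pass the filter only through later signal, which may raise these counts and this median. The counts at 72 h were the same with quantile normalisation and with median centring. The histone variants H2AX, H2AZ1 and H2AZ2 were at -1.36, -0.96 and -0.92 at 72 h, each called lower.

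Some single genes outside the fixed lists, picked for their values, are given without a claim for a group. At 72 h GPM6A, a neuronal membrane glycoprotein, was at 3.09, DCX, a microtubule protein of migrating neurons, at 2.93, GRIA2, a glutamate receptor subunit, at 1.62, SYT4 at 1.56 and MAPT, which encodes tau, at 1.53.

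In all, 25 genes were called in opposite directions at different times with a direct test between these times. Of these 17 were higher at 24 h and lower at 72 h, and 6 the reverse. E2F7, a repressor of E2F targets, went from 0.61 to -1.31, LIG1, a DNA ligase of replication, from 0.44 to -1.21, TIMELESS from 0.35 to -1.50, and IDS from -0.81 to 0.42.

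The p53 targets may move earlier than the cell-cycle genes. At 24 h the mean change of the p53 targets had reached 50.7 ± 9.45% of its 72 h size (SD, n = 3), that of the G1/S genes 12.2 ± 0.635% and that of the G2/M genes 2.22 ± 4.36%. The lowest 24 h array of the p53 targets lay 29.8 percentage points above the highest array of either cell-cycle list. At 48 h the shares were 80.7%, 69.3% and 50.3%. The shares depend on the choice of 72 h as the end. A list that still moved between 48 h and 72 h has a smaller share at 24 h by that choice. Each SD holds only the spread of the 24 h arrays and not that of the 0 h and 72 h arrays. The order in time does not show that the former acts on the latter.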
